A study of Mus musculus with 16 samples.

How the data were processed

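RNA was measured in 16 libraries from bone marrow of C57BL/6 mice, 4 each for BM pDC and for the progenitor populations DN, SP and DP. Per the labels' protocols, total RNA was isolated with a micro-scale column kit, amplified with SMART-Seq v4 and made into libraries with Nextera XT. Per the submitters' processing notes, reads were aligned with STAR to mm10, with no versions. The counting tool, its annotation and its strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The deposited table holds raw read counts per gene for 24454 Entrez genes, whole numbers whose sums differ between libraries. Gene names and coordinates (mm10) come from the RefSeq annotation of GRCm38.p6. The 80 genes without a current symbol (0.39% of counts) stayed in the table under their Entrez number but were not named, and 6260 genes had no counts.

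Depth was 19.4 to 48.7 M counts per library, with group means of 36.2 ± 11.3 in DN, 30 ± 7.3 in SP, 32.2 ± 3.8 in DP and 39.1 ± 9.5 M in BM pDC, and 14485 to 15401 genes detected. The protocol names no molecular tags, so PCR copies are counted as reads, and intervals printed on counts cover counting error only.

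Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Genes were filtered with filterByExpr, which left 13687, and libraries scaled by TMM, whose factors were 0.713 to 0.814 in BM pDC and 0.972 to 1.216 elsewhere. A quasi-likelihood model with 1 term per group was fitted to all 16 libraries, with 12 residual degrees of freedom and a biological coefficient of variation of 41.3%. The 6 pairwise comparisons used the quasi-likelihood F test at a Benjamini-Hochberg adjusted p of 0.05. The groups, comparisons, tests, gene lists, rule for named genes and most of the alternatives below were fixed before the data were examined.

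In all 27 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 162 tests. They cover sort markers, pDC surface genes and transcription factors, B-lineage, early lymphoid, T and innate lymphoid, stem, myeloid, conventional dendritic, antigen presentation, sensing, interferon, secretory, cell cycle, ribosome biogenesis, chemokine receptor, E protein and stress genes, and markers of erythroid, neutrophil, natural killer, plasma, basophil, megakaryocyte, macrophage, mature T and stromal cells. Similarity to BM pDC was Spearman's rho over the tested genes, leaving out the same mouse, with exact two-sided permutation tests of libraries, unpaired. Named genes were the 3 sort markers and 13 regulators whatever their outcome, up to 8 genes each way with the largest called fold per neighbouring comparison (mean of at least 20 CPM, no overlap between libraries), and up to 4 members per list. From these, 223 gene results were carried through the alternatives; which list members and top genes to carry was chosen after seeing the data. Results whose call ended when a library was left out were kept among them. Pax5 had 0 counts in BM pDC and 1 in DP, and no fold is given for that pair.

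The same number in different groups marks the same mouse, from the sample titles and the protocol. Deviations from the group means correlated at a mean r of 0.094 over 24 same-number pairs of libraries (11 over 0.1) and -0.031 over 72 other pairs (26 over 0.1). The ranges overlapped, at -0.581 to 0.578 for same-number pairs and -0.578 to 0.765 for the others. The highest pair was DN replicate 9 with BM pDC replicate 8, and the lowest DN replicate 8 with BM pDC replicate 8. The pairing thus rests on the labels, and the expression values neither bear it out nor exclude it. The model had no term for the mouse, and a fit with the mouse as a block was run beside it.

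The gene test was checked on simulated counts with 200 changed genes among 13687. It recovered 1.5%, 11.9% and 68.2% of genes changed 1.5-fold, 2-fold and 4-fold for SP against DN, 0%, 9% and 56.1% for DP against SP, and 0%, 10.4% and 63.6% for BM pDC against DP, with 1 false call in each. In this simulation most changes of 1.5-fold and 2-fold, and many of 4-fold, were therefore missed at 4 libraries per group. The adjusted threshold is less strict where more genes change, and up to 6664 genes were called in the data. Recovery with that many changed genes was not simulated and may be higher.

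Alternatives were the replicate block, other scalings (RLE, upper quartile), DESeq2, voom with quality weights, other count filters, only the 8 libraries compared, a threshold of 0.01, a test against a 1.5-fold change, and each library left out in turn. For lists they were an estimated correlation and fry, and for similarity Pearson's r and a mean of all 4 BM pDC libraries. Chosen after seeing the data were library totals alone, offsets for GC content and transcript length (known for 98.9% of genes) with and without the block, exact sign flips within the mouse for similarity, and a fit of 14 libraries without DN replicate 9 and BM pDC replicate 8. For the globin ratio and the other erythroid genes the condition under which a source counts as excluded or matched was made stricter after the values were known, so that 1 library or wide spread leaves it open.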

Results

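The series holds 16 RNA-seq libraries from mouse bone marrow: 3 populations of IL7R-expressing lymphoid progenitors named DN, SP and DP, and mature bone marrow plasmacytoid dendritic cells (BM pDC). Each population was taken from the same 4 mice, numbered 2, 5, 8 and 9, so n = 4 libraries per group throughout. The comparisons ask how the progenitor populations differ from each other and how near each lies to the mature cell. Values are CPM scaled by TMM (counts relative to library size; mean ± SD) and log2 differences (± SE); adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13687 genes, and those for gene lists from limma's camera over 162 tests.

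Siglech, a surface lectin of pDC, stood at 120 ± 47.2 CPM in DN, 361 ± 98.9 in SP, 2280 ± 298 in DP and 8460 ± 1110 in BM pDC. Ly6d, a lymphoid surface antigen, stood at 13.3 ± 6.19, 1280 ± 695, 2940 ± 359 and 2620 ± 764 CPM. Il7r, the interleukin 7 receptor chain used to sort the progenitors, stood at 750 ± 336, 1030 ± 447, 916 ± 285 and 630 ± 175 CPM and was not called between neighbouring populations. The sample labels used here do not state the gates. From knowledge of the study, Siglech and Ly6d are taken as the markers on which these populations were gated, so their differences are no finding. Ly6d separated DN from SP (6.59 ± 0.48, adjusted p = 1.01e-06) and Siglech separated SP from DP (2.66 ± 0.3, adjusted p = 2.97e-05). Of the 3 sort markers, 2 were higher in SP than DN and 2 in DP than SP, with the same counts adjusted over the list alone (camera adjusted p = 6.1e-16 and 0.00486); in BM pDC against DP 1 was higher and the set was not called (adjusted p = 0.548). The difference of Ly6d between DP and SP (1.2 ± 0.38, adjusted p = 0.0433) lost its call when any 1 of the 8 libraries other than SP replicate 5 was left out (adjusted p from 0.0617 to 0.128).

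The first principal component held 56% of the variance and separated BM pDC (scores 143 to 151.7) from DP (-11.8 to -6.7) and from DN (-81.5 to -64.8) and SP (-69.4 to -65.1), which overlapped. The second held 13.8%, and DN replicate 9 (-100.3) and BM pDC replicate 8 (-80.5) lay at its low end.

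**Figure D1:**
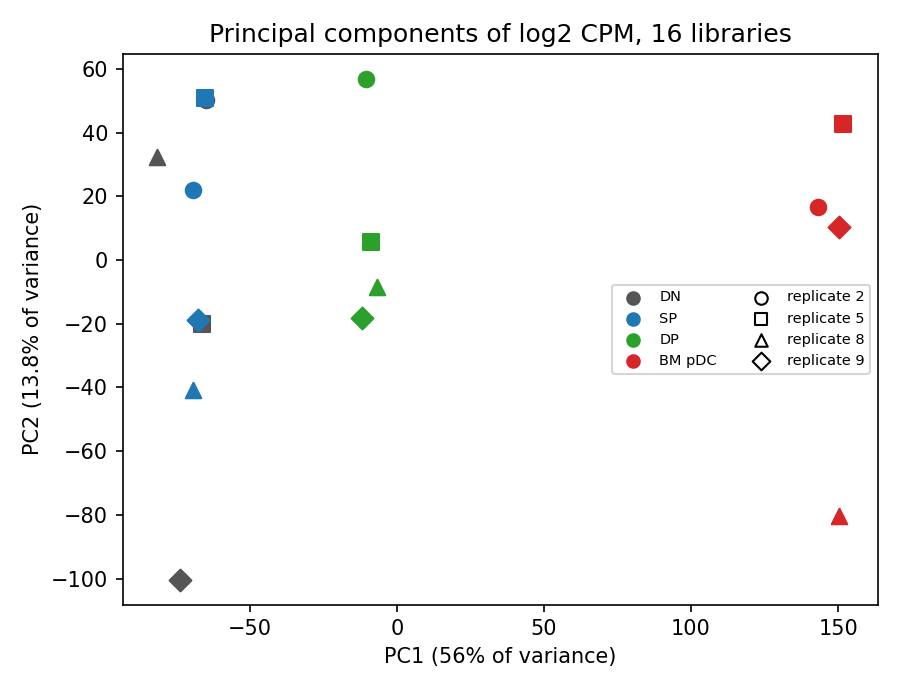
Scores of the 16 libraries on the first and second principal components of log2 CPM over the tested genes; each point is a library, coloured by population and marked with its replicate number. The first component (56% of the variance) places DP between the DN and SP libraries and the BM pDC libraries.

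Across the 13687 tested genes, each progenitor library was compared with the mean of the BM pDC libraries of the other 3 mice. Spearman's rho was 0.838 ± 0.016 for DN, 0.845 ± 0.008 for SP and 0.894 ± 0.007 for DP. DP lay nearer to BM pDC than DN did (difference 0.057) and than SP did (0.049), each with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allows, and an adjusted p of 0.0429 over 3 comparisons. SP and DN differed by 0.008 (exact permutation p = 0.429). This test ignores the mice. An exact permutation test by sign flips within each mouse, chosen after seeing the data, gave p = 0.125 for DP against DN and DP against SP, the smallest that 4 mice allow, so this paired test cannot pass; DP lay nearer in 4 of 4 mice in both. These are correlations across genes, which are not independent replicates; the libraries are the units of the test.

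Genes of the B lineage were higher in SP than in DN. Cd79a, a signalling chain of the B cell receptor (chromosome 7, 24897497 to 24901858), was higher in SP by 8.22 ± 0.56 (122 ± 24.7 against 0.417 ± 0.22 CPM, adjusted p = 9.87e-07), and Vpreb3, a pre-B cell receptor component (chromosome 10, 75943024 to 75949657), by 6.61 ± 0.47 (49.6 ± 1.68 against 0.501 ± 0.194 CPM). Igll1, the surrogate light chain (chromosome 16, 16860671 to 16863985), was higher by 8.96 ± 0.88, from 8 counts over the DN libraries, and Pou2af1, a B cell transcriptional coactivator, by 7.26 ± 1.02. The B-lineage regulator Ebf1 was higher by 4.17 ± 0.62 (110 ± 26.9 against 6.11 ± 3.42 CPM, adjusted p = 0.002) and the recombinase gene Rag1 by 3.51 ± 0.63 (adjusted p = 0.00784). Pax5, which fixes B cell identity, had 101 counts over the SP libraries and 1 over the DN libraries, a log2 ratio of 6.83 with a 95% counting interval of 4.32 to 12.15.

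Of 24 tested B-lineage genes, 18 were higher in SP, 0 lower and 6 not called, with 21 higher when adjusted over the list alone. As a set, B-lineage genes had an adjusted p of 9.73e-103 by camera, and adjusted p = 3.4e-06 with an estimated correlation. The mean log2 CPM of the list was even among the SP libraries (4.899, 4.811, 4.825 and 4.911 in replicates 2, 5, 8 and 9), whereas that of plasma cell markers was not (2.954, 1.59, 2.379 and 3.702). Vpreb2, also higher (5.78 ± 0.45), shares sequence with Vpreb1, so its share of the reads is uncertain. Other genes with the largest rises were Gfra2 (6.39 ± 1.01) and Gpat3, an acyltransferase (5.4 ± 0.38). Among early lymphoid genes 2 of 18 were higher and 16 not called, with 2 adjusted over the list alone; the adaptor gene Lax1 rose by 1.25 ± 0.21, and the set was called by camera (adjusted p = 0.022, and adjusted p = 0.104 with an estimated correlation), a call also lost without DN replicate 2 or 9 or SP replicate 5. Dntt, the terminal transferase of early lymphoid cells, stood at 4560 ± 653 CPM in SP and 4320 ± 1090 in DN (0.08 ± 0.23, adjusted p = 0.956).

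Few genes of the pDC programme separated SP from DN. Spib, a transcription factor of pDC and B cells, rose by 2.57 ± 0.31 (39 ± 7.82 against 6.57 ± 2.79 CPM, adjusted p = 0.000272) as the 1 called member of 15 pDC transcription factors (1 adjusted over the list alone; adjusted p = 0.00637, and adjusted p = 0.261 with an estimated correlation). Tcf4, the E protein required for pDC (0.04 ± 0.19), Irf8 (0.33 ± 0.48), Runx2 (0.23 ± 0.19), Bcl11a (0.02 ± 0.33) and Zeb2 (0.37 ± 0.21) were not called. Of 25 pDC surface and effector genes 1 was called higher, the chemokine receptor gene Ccr9 (1.65 ± 0.35, adjusted p = 0.0251), again 1 adjusted over the list alone. As a set, pDC surface and effector genes had an adjusted p of 0.0119 by camera, and adjusted p = 0.266 with an estimated correlation. Flt3 (-0.68 ± 0.61) and Kit (-0.78 ± 0.37) were not called, nor was Id2, an inhibitor of E proteins (-1.49 ± 0.41, adjusted p = 0.0927). Id2 passed with DESeq2 (-1.51, adjusted p = 0.0118), without DN replicate 8 (-1.70, 0.0453), without DN replicate 9 (-1.70, 0.0405) and with 14 libraries (-1.72, 0.0389), but stood at -0.816 (adjusted p = 0.318) without DN replicate 2, where it had 114 CPM against 48.7, 25.7 and 26.6 in the other DN libraries. The call of Ccr9 ended without DN replicate 2, 8 or 9 or SP replicate 5 or 8 (adjusted p from 0.0557 to 0.09) and with 14 libraries, a choice made after seeing the data (1.57, adjusted p = 0.0574).

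Members of the stem cell, myeloid and dendritic cell lists were among the 74 genes lower in SP than DN. Of 21 stem and multipotent progenitor genes 2 were lower and 19 not called, 5 lower adjusted over the list alone: Hlf, a stem cell transcription factor, fell by 1.98 on the log2 scale (SE 0.31) and Cd34 by 1.17 (SE 0.24, adjusted p = 0.0166). As a set, stem and multipotent progenitor genes had an adjusted p of 3.61e-07 by camera, and adjusted p = 0.0118 with an estimated correlation. The call of Cd34 ended without DN replicate 8 or SP replicate 2, 8 or 9 (adjusted p from 0.0537 to 0.0742). Of 22 myeloid progenitor genes 2 were lower and 20 not called, 4 adjusted over the list alone, with Csf3r, the G-CSF receptor, at -1.76 ± 0.28 (set adjusted p = 0.0146; adjusted p = 0.36 with an estimated correlation). Over myeloid progenitor genes the mean log2 CPM was 5.133 in DN replicate 2 and 4.016, 3.662 and 3.915 in replicates 5, 8 and 9; over basophil and mast cell markers it was 4.207, 0.81, 0.241 and 0.12, and 2.682 in SP replicate 5.

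Of 21 conventional dendritic cell genes 4 were lower in SP and 17 not called, 1 higher and 12 lower when adjusted over the list alone. As a set, conventional dendritic cell genes had an adjusted p of 1.77e-09 by camera, and adjusted p = 0.0531 with an estimated correlation. Xcr1, a chemokine receptor of cross-presenting dendritic cells, stood at -4.44 ± 0.58 (0.395 ± 0.147 against 8.53 ± 6.52 CPM) and Naaa at -2.87 ± 0.41. Of 23 antigen presentation genes 4 were lower and 19 not called, 6 adjusted over the list alone: Cd74, the MHC class II invariant chain, at -3.51 ± 0.64, H2-Eb1 at -3.73 ± 0.68, H2-Ab1 at -2.77 ± 0.5 and H2-Aa at -3.56 ± 0.69. Without DN replicate 2 these 4 differences were smaller, at -2.38, -2.7, -2.18 and -2.66. As a set, antigen presentation genes had an adjusted p of 0.000559 by camera, and adjusted p = 0.24 with an estimated correlation. The call of H2-Aa ended without SP replicate 9 (-3.55, adjusted p = 0.0649), as did that of Clec9a, a dendritic cell lectin (-2.99 ± 0.59; -2.91 and 0.0693 without it). The call of Batf3, a dendritic cell transcription factor (-3.29 ± 0.78, adjusted p = 0.0462), and that of Ccr2 (-2.33 ± 0.54, adjusted p = 0.0418) ended when any 1 of the 8 libraries other than DN replicates 8 and 9 was left out (adjusted p from 0.0665 to 0.161 and from 0.0852 to 0.148). The summed MHC class II genes varied within DN, at 4980, 1760, 553 and 836 CPM in replicates 2, 5, 8 and 9. Also lower were the transcription factor gene Nfil3 (-2.27 ± 0.35) and Ddx4 (-3.56 ± 0.67, adjusted p = 0.0111), whose call ended without SP replicate 2, 8 or 9 (adjusted p from 0.0503 to 0.0563).

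In all, edgeR called 201 genes between SP and DN, 127 higher and 74 lower; 1255 had an unadjusted p under 0.05. The count moved more than 1.5 times with DESeq2 (414), with voom (342), with only the 8 libraries compared (99), without SP replicate 8 (125) and without SP replicate 9 (115). Genes called higher and lower numbered 242 and 172 with DESeq2, 186 and 156 with voom and 74 and 25 with only the 8 libraries compared. With 1 library left out those higher numbered 86 to 129 and those lower 29 to 82; the lower count was 48 without DN replicate 2 and 35, 31 and 29 without SP replicates 2, 8 and 9. None of 42 cell cycle genes was called, 0 adjusted over the list alone, though the set lay lower in SP (median -0.58, adjusted p = 8.95e-11; adjusted p = 0.236 with an estimated correlation). The mean log2 CPM of these genes was 7.383, 7.177, 6.356 and 6.174 in SP replicates 2, 5, 8 and 9 and 7.743, 7.494, 7.412 and 6.921 in those of DN, so most of the difference lay in replicates 8 and 9.

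DP differed from SP by higher pDC genes and lower B-lineage genes. Spib was higher by 4.13 ± 0.33 (684 ± 205 against 39 ± 7.82 CPM, adjusted p = 2.29e-06; chromosome 7, 44525995 to 44532087), Tcf4 by 1.72 ± 0.19 (925 ± 57.8 against 280 ± 78.1 CPM, adjusted p = 2.88e-05), Irf8, a transcription factor of dendritic cells, by 2.09 ± 0.5 and Runx2, which serves pDC egress from marrow, by 1.86 ± 0.19. Zeb2, a repressor active in the pDC lineage, rose by 0.82 ± 0.21; Bcl11a (0.73 ± 0.33, adjusted p = 0.17), Flt3 (-0.15 ± 0.6), Kit (-0.93 ± 0.38) and Id2 (0.22 ± 0.4) were not called. Of 15 pDC transcription factors 5 were higher and 10 not called, 5 adjusted over the list alone. Together the pDC transcription factors had an adjusted p of 6.52e-05 by camera, and adjusted p = 0.115 with an estimated correlation. Of 25 pDC surface and effector genes 16 were higher, 0 lower and 9 not called, 17 adjusted over the list alone, among them Bst2, the tetherin antigen of pDC (2.28 ± 0.29), Cd300c (3.34 ± 0.45), the phosphatase gene Ptprf (3.84 ± 0.42) and Upb1 (4.77 ± 0.51). As a set, pDC surface and effector genes had an adjusted p of 3.07e-16 by camera, and adjusted p = 0.00199 with an estimated correlation.

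**Figure D2:**
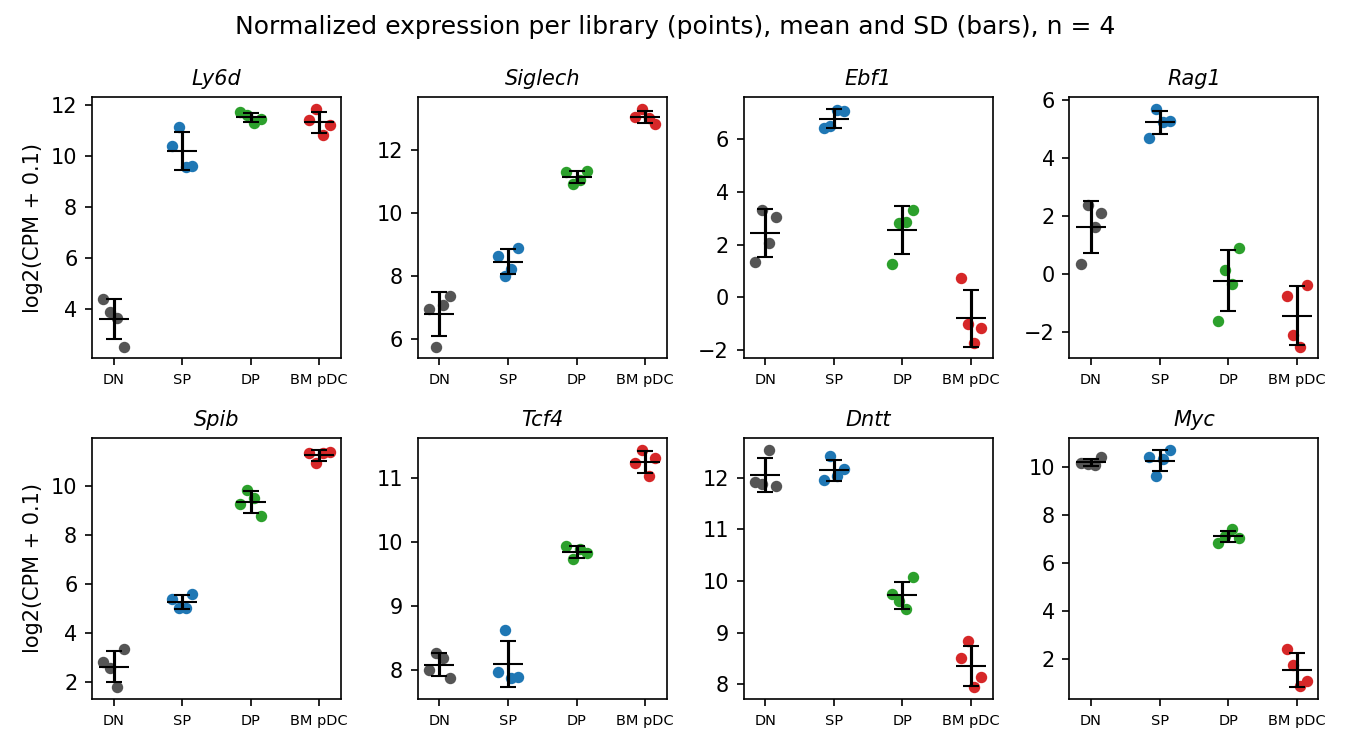
Levels of Ly6d, Siglech, Ebf1, Rag1, Spib, Tcf4, Dntt and Myc in DN, SP, DP and BM pDC as log2(CPM + 0.1); points are libraries (n = 4) and bars the mean and SD. Ebf1 and Rag1 are highest in SP, while Spib and Tcf4 are higher in DP and higher again in BM pDC.

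The B-lineage genes moved the other way. Pou2af1 fell by 9.36 on the log2 scale (SE 1.19) with 4 counts over the DP libraries, Igll1 by 9.07 (SE 0.89) with 7, Vpreb3 by 5.32 (SE 0.44), Rag1 by 5.35 (SE 0.69) and Ebf1 by 4.08 (SE 0.62, adjusted p = 0.000357). Pax5 had 1 count over the DP libraries, a log2 ratio of -6.61 with a 95% counting interval of -11.93 to -4.1. Of 24 B-lineage genes 2 were higher, 15 lower and 7 not called, 2 and 15 adjusted over the list alone. As a set, B-lineage genes had an adjusted p of 1.16e-14 by camera, and adjusted p = 0.00503 with an estimated correlation. Of 18 early lymphoid genes 1 was higher, 8 lower and 9 not called, 2 and 9 adjusted over the list alone, with Lax1 at -3.32 ± 0.22, Rag2 at -2.47 ± 0.29 and Dntt at -2.41 ± 0.24. As a set, early lymphoid genes had an adjusted p of 3.54e-07 by camera, and adjusted p = 0.00211 with an estimated correlation. Of 21 stem and multipotent progenitor genes 8 were lower and 13 not called, 11 adjusted over the list alone: Cd34 fell by 2.31 (SE 0.24) and Egfl7 by 2.13 (SE 0.25) on the log2 scale. As a set, stem and multipotent progenitor genes had an adjusted p of 1.47e-06 by camera, and adjusted p = 0.0122 with an estimated correlation.

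Growth and division genes parted. Of 42 cell cycle genes 28 were higher in DP, 0 lower and 14 not called, 39 adjusted over the list alone, such as the ribonucleotide reductase gene Rrm2 (1.94 ± 0.33), the cyclin gene Ccne1 (1.57 ± 0.29), the topoisomerase gene Top2a (1.69 ± 0.35) and the spindle motor gene Kif11 (1.86 ± 0.39). As a set, cell cycle genes had an adjusted p of 2.29e-17 by camera, and adjusted p = 0.12 with an estimated correlation. Of 32 ribosome biogenesis and Myc-target genes 14 were lower and 18 not called, 22 adjusted over the list alone. As a set, ribosome biogenesis and Myc-target genes had an adjusted p of 7.49e-10 by camera, and adjusted p = 0.0399 with an estimated correlation. Myc itself fell by 3.2 on the log2 scale (SE 0.32; 140 ± 24.1 against 1280 ± 361 CPM) and the nucleolar gene Gnl3 by 1.64 (SE 0.24).

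Sensing and dendritic cell genes were among those higher in DP. Of 22 myeloid progenitor genes 5 were higher, 2 lower and 15 not called, 5 and 4 adjusted over the list alone, and the set was not called (adjusted p = 0.867). Of 26 nucleic acid sensing genes 7 were higher and 19 not called, 8 adjusted over the list alone: the nuclease gene Pld4 by 2.34 ± 0.35, Unc93b1, the chaperone of endosomal Toll-like receptors, by 1.61 ± 0.3, and the lysosomal genes Ctsb (2.48 ± 0.27) and Grn (2.64 ± 0.32). As a set, nucleic acid sensing genes had an adjusted p of 0.000326 by camera, and adjusted p = 0.0672 with an estimated correlation. Of 21 conventional dendritic cell genes 8 were higher, 1 lower and 12 not called, 8 and 2 adjusted over the list alone, including the integrin gene Itgax (3.33 ± 0.26), Clec10a (2.39 ± 0.36) and Sirpa (2.03 ± 0.33). As a set, conventional dendritic cell genes had an adjusted p of 0.00016 by camera, and adjusted p = 0.175 with an estimated correlation. Clec10a, Sirpa and Clec9a were higher again in BM pDC (345 to 619, 303 to 649 and 91.7 to 150 CPM) than in DP (27.1 to 46.7, 35.8 to 68.6 and 4.41 to 10.6). Batf3, Tlr3 and Xcr1 of the list stood at 0.0237 to 0.254, 0 to 0.464 and 0.378 to 1.27 CPM in DP. The rises thus do not by themselves mark conventional dendritic cells. Of 31 interferon-stimulated genes 3 were higher, 12 lower and 16 not called, 4 and 13 adjusted over the list alone, with Rtp4 at -4.53 ± 0.53, Ifit1 at -2.3 ± 0.37 and Ddx58 at -2.22 ± 0.29. As a set, interferon-stimulated genes had an adjusted p of 0.0121 by camera, and adjusted p = 0.611 with an estimated correlation. Of 39 secretory pathway genes 5 were higher and 34 not called, 5 adjusted over the list alone, with Dnajb11, a chaperone of the endoplasmic reticulum, at 0.86 ± 0.17. As a set, secretory pathway genes had an adjusted p of 0.0109 by camera, and adjusted p = 0.282 with an estimated correlation. Hsp90b1, another such chaperone (0.95 ± 0.24, adjusted p = 0.0135), lost its call without SP replicate 8 (0.88, adjusted p = 0.0514), without SP replicate 9 (0.89, 0.0518) or without DP replicate 2 (0.77, 0.0518). Other genes among the largest rises were Havcr1 (4.78 ± 0.51), the GTPase gene Rnd3 (4.14 ± 0.61), Cd7 (4.02 ± 0.37) and Cdh1, E-cadherin (3.76 ± 0.51).

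In all 2097 genes were called, 1019 higher and 1078 lower (48.6% higher); with library totals alone as scaling 33.9% of 2469 were higher. With voom the count was 3747.

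DP was also set against DN, without assuming that SP lies between them. Spib was higher by 6.7 ± 0.37 (adjusted p = 2.7e-08), Siglech by 4.24 ± 0.32, Irf8 by 2.42 ± 0.51, Runx2 by 2.09 ± 0.19, Tcf4 by 1.76 ± 0.19 and Zeb2 by 1.19 ± 0.21. Cd34 stood lower, at -3.48 ± 0.26, as did Myc at -3.09 ± 0.32, Dntt at -2.33 ± 0.24 and Kit, the stem cell factor receptor, at -1.72 ± 0.38. Ebf1, called higher in SP than in either, stood at 6.51 ± 3.08 CPM in DP and 6.11 ± 3.42 in DN (0.1 ± 0.55, adjusted p = 0.934). Id2 was at -1.27 ± 0.4 (adjusted p = 0.0419). Its call ended without DN replicate 2 (-0.591, adjusted p = 0.195), without DN replicate 5 or any 1 DP library (adjusted p from 0.0623 to 0.0973) and with the replicate block (-1.04, adjusted p = 0.0583).

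Of 25 pDC surface and effector genes 18 were higher in DP than DN and 7 not called, 19 adjusted over the list alone, and of 15 pDC transcription factors 6 were higher and 9 not called, 6 and 1 lower adjusted over the list alone (adjusted p = 2.31e-07; 0.0399 with an estimated correlation). As a set, pDC surface and effector genes had an adjusted p of 6.63e-21 by camera. Of 24 B-lineage genes 11 were higher and 13 not called, 12 adjusted over the list alone. As a set, B-lineage genes had an adjusted p of 1.13e-06 by camera, and adjusted p = 0.0399 with an estimated correlation. The members were mixed. Fcrla (20.7 to 40.6 CPM in DP, 1.01 to 4.23 in DN) and Mzb1 (7.78 to 10.9 and 2.26 to 5.03) were higher still in BM pDC (243 to 364 and 138 to 279). Blk (342 to 446 and 38.6 to 144) and Cd79a (3.4 to 5.21 and 0.125 to 0.613) were also higher. Igll1 and Pou2af1 reached at most 0.142 and 0.143 CPM in DP, and 0.175 and 0.33 in DN. Of 21 stem and multipotent progenitor genes 14 were lower and 7 not called, 17 adjusted over the list alone, and of 32 ribosome biogenesis and Myc-target genes 23 were lower and 9 not called, 28 adjusted over the list alone (adjusted p = 4.51e-13; 0.0207 with an estimated correlation). As a set, stem and multipotent progenitor genes had an adjusted p of 1.84e-13 by camera.

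In all 2223 genes were called, 959 higher and 1264 lower (43.1% higher); 53.9% were higher with offsets for GC content and length and 55.8% with the block added, choices made after seeing the data. Genes called in the same direction for DP against DN and for BM pDC against DN numbered 1736, 733 higher and 1003 lower, and 164 went opposite ways. Of the genes called for DP, 76.4% of those higher and 79.4% of those lower were also called for BM pDC. Both comparisons share the DN libraries: 20 simulations with unchanged groups gave a mean overlap of 0, but at most 1 call each, so they say little about what shared controls add among called genes. Independent lists of these sizes would share 203.3 higher and 347.5 lower genes. With 2 DN libraries for each comparison the overlap had a median of 1076.5 over 6 splits, where independent lists would share a median of 351.15, and at an adjusted p under 0.01 it was 914.

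BM pDC differed from DP by higher mature surface and antigen presentation genes and by lower division genes. Cd4, a coreceptor also carried by pDC, was higher by 7.09 ± 0.3 (822 ± 93.9 against 6.01 ± 0.933 CPM, adjusted p = 4.44e-10; chromosome 6, 124864693 to 124888247). Irf7, the master regulator of type I interferon genes, was higher by 3.9 ± 0.33 (2610 ± 572 against 175 ± 29.7 CPM), Ccr9 by 4.41 ± 0.4 and Slamf9 by 9.04 ± 0.92 (chromosome 1, 172458569 to 172478421). Cdca7, a gene of dividing cells, stood at -5.11 ± 0.25 and Cd34 at -6.38 ± 0.3.

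Of 25 pDC surface and effector genes 22 were higher and 3 not called, 22 adjusted over the list alone. As a set, pDC surface and effector genes had an adjusted p of 2.85e-19 by camera, and adjusted p = 0.00183 with an estimated correlation. Of 15 pDC transcription factors 6 were higher and 9 not called, 6 adjusted over the list alone: Tcf4 rose by 1.42 ± 0.19 and Spib by 1.86 ± 0.3, while Irf8 (0.68 ± 0.49), Bcl11a (0.53 ± 0.33), Zeb2 (0.35 ± 0.21) and Runx2 (0.43 ± 0.19, adjusted p = 0.0802) were not called. Together the pDC transcription factors had an adjusted p of 0.011 by camera, and adjusted p = 0.3 with an estimated correlation. Runx2 passed with DESeq2 (0.48, adjusted p = 0.0483) and without BM pDC replicate 9 (0.54, adjusted p = 0.0415), and ranged from 0.339 to 0.544 with 1 library left out. The largest rises by fold held Myh13 (9.65 ± 0.8, from 5 counts over the DP libraries), Ttc39a (9.23 ± 0.73, from 4) and the kallikrein genes Klk1 (9.06 ± 0.59), Klk1b3, Klk1b5 and Klk1b27. The kallikreins, and Cd209d (8.79 ± 0.61), Klra17 (6.27 ± 0.54), Duxbl1 (8.8 ± 0.9) and Ly6c2 (4.84 ± 0.45), have near-identical relatives, so which copy the reads came from is uncertain.

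Of 23 antigen presentation genes 17 were higher, 1 lower and 5 not called, 19 and 1 adjusted over the list alone. As a set, antigen presentation genes had an adjusted p of 2.7e-09 by camera, and adjusted p = 0.0531 with an estimated correlation. The MHC class II gene H2-Ab1 rose by 7.04 ± 0.61 (5870 ± 1470 against 44.5 ± 14.3 CPM) and H2-Oa by 3.8 ± 0.31, while H2-Ob, which encodes its partner chain, fell by 3.45 on the log2 scale (SE 0.26). Of 26 nucleic acid sensing genes 14 were higher, 1 lower and 11 not called, 14 and 1 adjusted over the list alone. The listed Toll-like receptor gene Tlr12, not itself a known receptor of nucleic acid, stood at 3.23 ± 0.37. As a set, nucleic acid sensing genes had an adjusted p of 2.6e-05 by camera, and adjusted p = 0.0399 with an estimated correlation. Of 31 interferon-stimulated genes 22 were higher and 9 not called, 23 adjusted over the list alone: Oasl2 by 3.33 ± 0.35, Ifit1 by 2.96 ± 0.37 and Zbp1 by 2.63 ± 0.3. As a set, interferon-stimulated genes had an adjusted p of 2.79e-07 by camera, and adjusted p = 0.27 with an estimated correlation. Of 39 secretory pathway genes 13 were higher and 26 not called, 9 adjusted over the list alone, with Edem2, of endoplasmic reticulum quality control, at 1.68 ± 0.28. As a set, secretory pathway genes had an adjusted p of 0.00834 by camera, and adjusted p = 0.27 with an estimated correlation. Of 19 chemokine receptor and trafficking genes 10 were higher, 4 lower and 5 not called, 13 and 4 adjusted over the list alone, with Ccr9 at 4.41 ± 0.4 and Ccr7, the lymph node homing receptor, at -2.39 ± 0.27. As a set, chemokine receptor and trafficking genes had an adjusted p of 0.00513 by camera, and adjusted p = 0.186 with an estimated correlation.

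Of 42 cell cycle genes 41 were lower in BM pDC and 1 higher, with the same counts adjusted over the list alone, such as the replication genes Mcm3 (-3.64 ± 0.23), Mcm4 (-3.19 ± 0.19) and Cdc6 (-4.53 ± 0.32). As a set, cell cycle genes had an adjusted p of 7.68e-35 by camera, and adjusted p = 0.0393 with an estimated correlation. Of 18 early lymphoid genes 1 was higher, 11 lower and 6 not called, 1 and 11 adjusted over the list alone, with Rag2 at -5.62 ± 0.35, Cd27 at -4.21 ± 0.27 and Dntt at -1.34 ± 0.23. As a set, early lymphoid genes had an adjusted p of 4.49e-10 by camera, and adjusted p = 0.000869 with an estimated correlation. Of 21 stem and multipotent progenitor genes 2 were higher, 10 lower and 9 not called, 2 and 12 adjusted over the list alone. As a set, stem and multipotent progenitor genes had an adjusted p of 0.00378 by camera, and adjusted p = 0.115 with an estimated correlation. Of 32 ribosome biogenesis and Myc-target genes 10 were lower and 22 not called, 9 adjusted over the list alone, and Myc fell by 5.53 on the log2 scale (SE 0.36). As a set, ribosome biogenesis and Myc-target genes had an adjusted p of 0.00847 by camera, and adjusted p = 0.332 with an estimated correlation. Of 24 B-lineage genes 7 were higher, 6 lower and 11 not called, 8 and 6 adjusted over the list alone, and the set was not called (adjusted p = 0.869); Mzb1, a chaperone of antibody-secreting cells, stood at 4.3 ± 0.32 and the kinase gene Blk at -3.38 ± 0.35. Ebf1 stood at -3.4 ± 0.63, Kit at -2.17 ± 0.39 and Rag1 at -1.43 ± 0.65 (adjusted p = 0.101); Rag1 passed without DP replicate 2 (-1.75, adjusted p = 0.0404) and without BM pDC replicate 9 (-2.04, adjusted p = 0.0465), but stood at -0.895 (adjusted p = 0.342) without DP replicate 9. Flt3 stood at -0.7 ± 0.61 and was not called. Id2 stood at -1.31 ± 0.41 (adjusted p = 0.0183), a call that ended without BM pDC replicate 9 (-1.21, adjusted p = 0.0556). Other large falls were those of Drc7 (-8.79 ± 0.38), the cytoskeletal gene Cttn (-7.1 ± 0.57), Pdgfrb (-6.41 ± 0.44) and Csf1r, the macrophage growth factor receptor (-5.37 ± 0.56).

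Of 13 erythroid marker genes 9 were higher in BM pDC than DP and 4 not called, 9 adjusted over the list alone, with the beta globin genes Hbb-bs at 78.7 ± 41.3 against 2.51 ± 2.98 CPM (4.95 ± 1.14) and Hbb-bt at 46.7 ± 26.1 against 1.71 ± 2.11 CPM, and Ermap at 5.78 ± 1.08 from 9 counts over the DP libraries. The globin genes have near-identical copies, so their separate values are uncertain. As a set, erythroid marker genes had an adjusted p of 0.00808 by camera, and adjusted p = 0.433 with an estimated correlation. Part of this contrast lay in low values of DP. The set was also lower in DP than SP, with 2 lower and 11 not called (camera adjusted p = 0.00665, and 0.423 with an estimated correlation). The mean log2 CPM of the list was -1.996 to 0.066 in DP, -0.961 to 1.113 in DN, -1.685 to 2.098 in SP and 1.774 to 3.494 in BM pDC. The 50 most abundant genes held 22.6 ± 1.7% of the counts in BM pDC, against 12.4 ± 0.5% in DP.

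**Figure D3:**
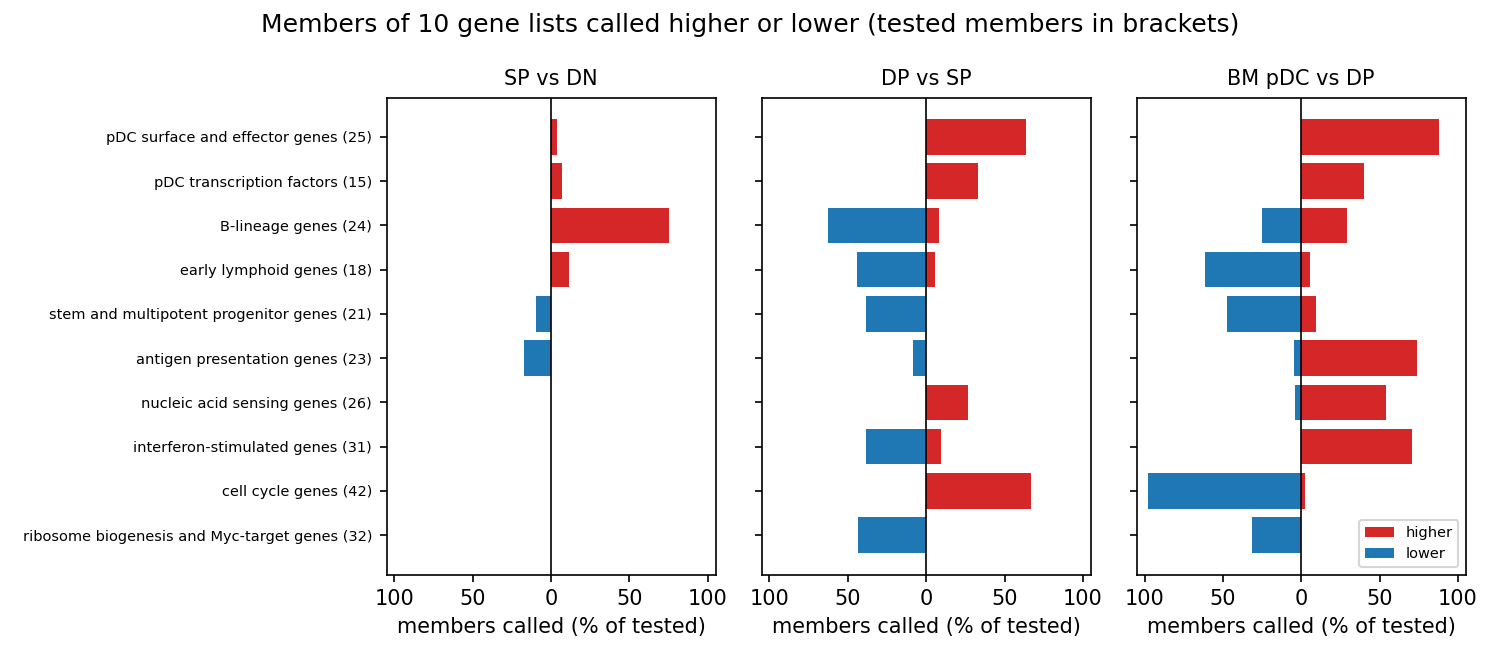
Percent of the tested members of 10 gene lists called higher or lower in SP vs DN, DP vs SP and BM pDC vs DP; bars start at 0 and each panel is a comparison. B-lineage genes are called higher in SP (18 of 24) and mostly lower in DP (15 of 24), and 41 of 42 cell cycle genes are lower in BM pDC than DP.

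In all 4973 genes were called between BM pDC and DP, 2404 higher and 2569 lower (48.3% higher); with library totals alone 26% of 5891 were higher. Against DN 6664 genes were called, 2901 higher and 3763 lower (43.5% higher; 24% of 7722 with library totals alone), and against SP 6377, 2834 higher and 3543 lower (44.4% higher; 21.7% of 7784). Library totals alone moved the median log2 difference of all genes to -0.363, -0.626 and -0.621 in these 3 comparisons, from 0.052, -0.133 and -0.048, and to -0.201 for DP against SP from -0.046.

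Against DN, Spib was higher in BM pDC by 8.56 ± 0.4, Tcf4 by 3.18 ± 0.2, Irf8 by 3.1 ± 0.52, Runx2 by 2.52 ± 0.2, Zeb2 by 1.54 ± 0.21 and Bcl11a, a transcription factor of the pDC and B lineages, by 1.28 ± 0.34 (adjusted p = 0.00501), and Id2 stood at -2.58 ± 0.42. Of 25 pDC surface and effector genes 23 were higher against DN and 22 against SP, with the same counts adjusted over the list alone. As a set, pDC surface and effector genes had an adjusted p of 7.48e-27 and 6.07e-26 by camera. Of 15 pDC transcription factors 10 were higher and 1 lower against DN and 11 and 1 against SP, again the same adjusted over the list alone. Together the pDC transcription factors had an adjusted p of 3.45e-06 and 3.3e-05 by camera, and adjusted p = 0.0531 and 0.1 with an estimated correlation. Of 18 early lymphoid genes 2 were higher in each, and 14 lower against DN and 12 against SP, 15 and 13 adjusted over the list alone. As a set, early lymphoid genes had an adjusted p of 6.03e-11 and 4.51e-13 by camera.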

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

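All tests in this part were chosen after the result was seen, apart from the splits of the libraries, which were planned. In 25 of 357 groups of 4 values, 1 library lay far from the other 3 (gap over range above Dixon's 95% critical value). Chance alone would give about 1 in 20, or 17.9. The 25 include Pax5 in DN and Pax5, Pou2af1 and Zbtb16 in DP, with counts in 1 library alone. Their ratio is 1 whatever that count, so the 25 cannot be set strictly against 17.9.

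Among DN libraries these were the total count (ratio 0.904; replicate 5, 19.4 M counts), Dntt (0.898; replicate 8, 5960 CPM against a median of 3790) and Pax5 (1; 1 count in replicate 9 and none in the others). Among SP libraries they were Tcf4 (0.875; replicate 5, 397 against 238 CPM), Rag2 (0.855; replicate 5, 364 against 224), Csf3r (0.832; replicate 5, 27.2 against 21.6) and Ccne1 (0.862; replicate 9, 2.46 against 5.43).

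Among DP libraries they were Pax5 (1; 1 count, in replicate 9), Pou2af1 (1; 4 counts, in replicate 5), Zbtb16 (1; 3 counts, in replicate 5), Unc93b1 (0.936; replicate 9, 1920 against 3420 CPM), Axl (0.838; replicate 9, 0.483 against 1.76), Hsp90b1 (0.866; replicate 2, 2590 against 1700), Vpreb2 (0.891; replicate 2, 0.327 against 0.554), Pdgfrb (0.922; replicate 2, 27.5 against 58.6), Prf1 (0.907; replicate 8, 11.4 against 7.54) and Cd14 (0.941; replicate 8, 0.168 against 0.331). Among BM pDC libraries they were Spib (0.862; replicate 5, 1960 against 2660 CPM), Zeb2 (0.953; replicate 5, 213 against 301), Csf1r (0.844; replicate 5, 4 against 6.42), Ermap (0.856; replicate 5, 2.49 against 4.07), Bcl11a (0.866; replicate 8, 666 against 341), Ccr7 (0.832; replicate 8, 24.4 against 34.2), Egfl7 (0.867; replicate 2, 1.31 against 1.92) and Dok3 (0.867; replicate 2, 9.06 against 7.1).

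The first pattern is an axis that held 45.4% of the variance within groups (the second axis 11.8%), with DN replicate 9 (score 90.9) and BM pDC replicate 8 (78) at one end and DN replicate 2 (-61.1) at the other. Removing each library's trend on GC content and length left the share at 44.2%, from 45.5%, which argues against the fitted trend as the main source. The weights of the genes on the axis still correlated with length (rho 0.3) and GC content (rho 0.2). RNA and library quality were not tested. Libraries of 1 mouse could lie together: 42.9% of the spread of scores lay between mice, where chance gives 25%, with a permutation p of 0.149 over 13824 arrangements, so a shared mouse can be neither shown nor excluded with 4 mice. Handling stress may contribute: of 19 immediate early and stress genes 11 lay in the top 25% of the axis, where 4.75 were expected. Junb, Ier2 and Hspa1a were among them, while Fos (percentile 38), Klf6 (7) and Hspa8 (1) were not. The mean log2 CPM of the list was raised in DN replicate 9 (5.594 against 2.929, 3.296 and 2.675 in replicates 2, 5 and 8). In BM pDC replicate 8 it was not (4.366 against 4.211, 4.483 and 4.573 in replicates 2, 5 and 9). The list as a whole thus does not mark that library. The list was highest in replicate 9 in DN (5.594), SP (4.491), DP (4.929) and BM pDC (4.573) alike. The axis did not follow this order throughout. Replicate 9 scored above replicate 8 in DN (90.9 against -41.8) and DP (26.6 against 17.6). It scored below replicate 8 in SP (22.1 against 44.5) and BM pDC (-12.8 against 78). A biological difference between the cells sorted each time stays open.

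The second pattern is the higher MHC class II and dendritic cell genes of DN. They do not rest on DN replicate 2 alone, since 7 of 8 called members stayed called without it (Batf3 was lost), though it adds to their size: Cd74 went from -3.51 to -2.38, H2-Eb1 from -3.73 to -2.7 and Clec9a from -2.99 to -2.19 without it. Other cells present in varying share are a candidate source: MHC class II genes ranged over 3.17 log2 units among the DN libraries while their ratio to the dendritic cell genes ranged over 0.86, with ratios of 43.9, 25.7, 24.2 and 26 in replicates 2, 5, 8 and 9. The summed MHC class II genes stood at 4980 CPM in replicate 2 and the 4 dendritic cell genes at 113 CPM; that library also scored highest on basophil and mast cell markers (mean log2 CPM 4.207 against 0.81, 0.241 and 0.12) and myeloid progenitor genes (5.133 against 4.016, 3.662 and 3.915). A programme carried by the DN cells themselves would give the same ratio and stays open, as the sort on IL7R was not tested for such cells.

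The third pattern is the erythroid genes higher in BM pDC than in DP. If they came from erythroid cells or their RNA, alpha and beta globin should keep 1 ratio: over 12 libraries with at least 100 counts of each the log2 ratio ranged over 2.4, and over 0.82 without DN replicate 9 (ratio 0.77, from 144 and 186 counts), while below that count the ratio was also low in DN replicate 8 (0.34; 90 and 267 counts), SP replicate 8 (0.59; 22 and 37) and DP replicate 5 (1.06; 18 and 17). The low ratios all lie outside BM pDC, so they leave its source open; after that result the BM pDC libraries were taken alone, where the ratio lay between 3.13 and 3.64 and ranged over 0.22, as 1 source would give. The summed counts of the other 5 called members, set against beta globin, differed by 0.26 log2 units between BM pDC and 8 other libraries, but ranged over 3.7 among those 8 and 1.35 within BM pDC, so this comparison cannot tell. Erythroid RNA is a candidate source, from tests on the same data, and expression by the sorted cells stays open.

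Splits of the 8 libraries of each comparison into 4 and 4, 35 in all, were counted for calls. Calls numbered 2574 for DP vs SP, 1530 for DP vs DN and 4858 for BM pDC vs DP. They numbered 5411 for BM pDC vs DN and 6257 for BM pDC vs SP. In each of these, 1 split, the real one, gave as many and the highest other gave 0. Most of the 35 splits ignore the mice. Only 8 part all 4 mice's pairs, too few for a share under 0.05, so with the mice kept the splits cannot exclude chance. The fit with the mouse as a block, which does not test the splits, called 2108, 2235, 4863, 6484 and 6380 genes. For SP vs DN 2 splits gave as many as the real 99, so chance cannot be excluded by this count. The other called 1720 genes, with SP replicates 2 and 5 and DN replicates 2 and 8 against the rest. These libraries had negative scores on the axis of the first pattern (-18.5, -48.1, -61.1 and -41.8). SP replicates 8 and 9 and DN replicates 5 and 9 had positive scores (44.5, 22.1, 12 and 90.9), so this split follows that axis. Among the 8 splits that part all 4 mice's pairs the highest other gave 0.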

How the results depend on the processing

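Library totals alone, the GC content and length offsets, the fit of 14 libraries and the sign flips within the mouse were chosen after the data were seen. The other alternatives were planned. Genes called for SP vs DN numbered 201 and ranged from 115 to 191 with 1 library left out, and were 414 with DESeq2, 342 with voom, 99 with only the 8 libraries compared, 92 at an adjusted p under 0.01 and 91 against a 1.5-fold change. For DP vs SP they were 3747 with voom, 1066 at 0.01 and 1009 against 1.5-fold, and for DP vs DN 1137 and 1064; fewer calls follow from the stricter thresholds, and the cause of the other shifts was not tested. The other counts lay within 1.5 times the values reported. The overlap fell to 914 at 0.01 and 1076.5 with split DN libraries, where fewer libraries are compared.

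With the replicate block the counts were 220 for SP vs DN and 92 list tests (90 without). It ended the list calls of ribosome biogenesis genes in SP vs DN (camera adjusted p = 0.0574 against 0.0435) and erythroid genes in DP vs DN (0.0554 against 0.041). It also ended the gene call of Id2 in DP vs DN (-1.04, edgeR adjusted p = 0.0583) and no other list or gene call reported. Of the 90 list calls 88 stayed, and sets that passed only with the block were not followed. With an estimated correlation 31 list tests passed, and 59 calls were lost; fry lost 12, RLE scaling 2 and left-out libraries 41 in all.

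An exact permutation test by sign flips within the mouse, chosen after seeing the data, left the similarity differences at 0.0567 for DP minus DN and 0.049 for DP minus SP with p = 0.125 (adjusted p = 0.188), the smallest possible with 4 mice. With 1 mouse left out, 3 against 3 cannot pass the exact test: the similarity differences ranged from 0.0464 to 0.061 for DP minus DN, 0.0425 to 0.0572 for DP minus SP and -0.0054 to 0.0184 for SP minus DN, reversed without replicate 9. Of 223 gene results 199 were called, and 13 of these lost the call in 1 or more leave-outs: Ccr9, Id3, Batf3, Ccr2, Cd34, Ddx4, H2-Aa and Clec9a in SP vs DN, Ly6d and Hsp90b1 in DP vs SP, Id2 in DP vs DN, and Id2 and Klrd1 in BM pDC vs DP. Id3 (1.97 ± 0.39, adjusted p = 0.0142) was lost without DN replicate 2 (1.9, 0.0526). Uncalled values near 0 changed sign when 1 library was left out: Bcl11a (-0.169 to 0.39), Tcf4 (-0.181 to 0.122; -0.029 with 14 libraries) and Dntt (-0.029 to 0.293) in SP vs DN, Il7r (-0.311 to 0.15) and Flt3 (-0.358 to 0.298) in DP vs SP and Ebf1 in DP vs DN (-0.166 to 0.423). The self-test recovered few 2-fold changes (11.9% for SP vs DN) and 68.2% of 4-fold changes there. An uncalled gene may thus have changed by 2-fold or more.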

Other observations

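The hypotheses weighed above are the only ones tested, and the values here were chosen after the data were seen. Receptor genes of natural killer cells moved apart between DP and SP: of 8 such markers 3 were higher, 2 lower and 3 not called (3 and 3 adjusted over the list alone; camera adjusted p = 0.861), with the receptor genes Klrd1 at 2.22 ± 0.28 and Klrk1 at 3.23 ± 0.57 and the granule gene Nkg7 at -3.49 ± 0.54. In BM pDC against DP, Klrd1 stood at 0.86 ± 0.27 (adjusted p = 0.0187), a call lost without DP replicate 5 (0.69, 0.0746), without DP replicate 8 (0.82, 0.0501) or without BM pDC replicate 2 (0.73, 0.0613). The endothelial cadherin gene Cdh5 was higher in SP than DN by 2.13 ± 0.4, from only 63 and 16 counts over the libraries. It was higher in DP than SP by 4.59 ± 0.37 and in BM pDC than DP by 2.1 ± 0.32. Of 5 stromal markers 2 were higher and 3 not called in DP against SP (3 higher and 1 lower adjusted over the list alone). That set had an adjusted p of 0.00719 by camera, and adjusted p = 0.0521 with an estimated correlation. In BM pDC against DP, Kdr, a vascular growth factor receptor, was higher by 7.51 ± 1. The stromal markers Pecam1 (273, 174, 199 and 229 against 400, 395, 372 and 420 CPM) and Sparc went the other way there, lower in every BM pDC library than in any DP library. Of 10 mature T cell markers 5 were higher, 2 lower and 3 not called in BM pDC against DP (5 and 2 adjusted over the list alone; adjusted p = 0.053), with Cd8b1 at 8.15 ± 0.56 and Cd6 at -4.77 ± 0.27. Of 21 T and innate lymphoid genes 7 were higher and 7 lower there (9 and 7 adjusted over the list alone; adjusted p = 0.612), with Cd7 at 2.51 ± 0.35, the kinase gene Lck at -4.11 ± 0.28 and the transcription factor gene Tox at -4.95 ± 0.45.

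Of 14 macrophage and monocyte markers 5 were higher, 1 lower and 8 not called in BM pDC against DP (5 and 1 adjusted over the list alone; adjusted p = 0.0116, and adjusted p = 0.387 with an estimated correlation), Cd14 at 3.83 ± 0.8 and Axl at 2.8 ± 0.58 among them. Of 8 E protein and Id genes 2 were higher and 6 not called in DP against SP (2 adjusted over the list alone; adjusted p = 0.0116, and adjusted p = 0.0592 with an estimated correlation), with Id3 at 2.62 ± 0.38. Of 6 megakaryocyte markers 1 was lower in DP than SP, Gp9 at -5.04 ± 0.56 from 9 counts over the DP libraries (1 adjusted over the list alone; adjusted p = 0.571). Of 19 immediate early and stress genes 5 were higher and 1 lower in BM pDC against DP (5 and 1 adjusted over the list alone; adjusted p = 0.137), with Btg2 at 3.79 ± 0.26. None of 15 neutrophil markers was called by edgeR in SP against DN, 0 adjusted over the list alone, though the set lay higher (median 0.8, adjusted p = 3.9e-07; adjusted p = 0.236 with an estimated correlation). None of 6 plasma cell markers was called there, 3 higher adjusted over the list alone (adjusted p = 0.000184; 0.0356 with an estimated correlation), and the antibody joining chain gene Jchain stood at 169, 3.39, 1.75 and 122 CPM in SP replicates 2, 5, 8 and 9. Of 10 basophil and mast cell markers 5 were lower in DP than DN and 5 not called (6 adjusted over the list alone; adjusted p = 0.0367, and adjusted p = 0.482 with an estimated correlation), and the mast cell protease gene Mcpt8 stood at 161, 1.62, 3.43 and 1.16 CPM in DN replicates 2, 5, 8 and 9.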
